A study of Rattus norvegicus with 18 samples.

How the data were processed

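Gene expression was measured in WB-F344 cells, a rat liver epithelial line with stem-like properties, grown to confluence at passages 14 to 16 and exposed to 100 nM PCB126 or to 0.1% DMSO as the vehicle for 6, 24 or 72 h. Each of the 6 combinations of treatment and time has 3 samples, which the labels call independent repeats, and each of the 18 samples has 1 array. Total RNA was fragmented, labelled with biotin and hybridised to an Affymetrix rat exon array, per the labels' protocols. The labels do not say whether the repeats were separate thaws or passages, so p-values measure the spread between these samples.

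The deposited table holds log2 expression values made by RMA with Affymetrix Power Tools 1.12.0, per the submitters' processing notes. RMA corrects background, normalises between arrays and summarises the probes of a probe set, and its version is not given in the sources used here. The table has 1044112 probe sets, with values between 0.247 and 15.2 on the log2 scale. Background correction and quantile normalisation compress fold changes of dim and very bright probe sets, so changes near either end of the scale are likely to be understated. Detection p-values were not used here, and the array build is not given in the sources used here. For arrays, their number (3 per group) limits the precision.

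The platform annotation paired 223110 probe sets with 1 gene symbol, 3523 with several and 817479 with none. A gene's value on an array was the median over the probe sets paired with that symbol and no other, which gave 16988 genes with a median of 10 probe sets each. Of these, 657 genes rested on 1 probe set. Probe sets with several symbols or none were left out of the gene values. Symbols are those of the platform annotation, which are partly old. Of them 12943 are current RefSeq symbols, 3982 are older symbols of 1 current gene and 63 had no match in the GRCr8 gene table, which was used for names alone. Genes with close paralogs (Akr1c14, Gstm1, Gstm2, the Ugt1a genes and keratins such as Krt18) can share probes with their relatives, so their values are uncertain in that respect.

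Differences were tested on the gene values with limma 3.58.1 in R 4.3.3, with matrixStats 1.5.0 and the package data.table (version 1.17.8) for handling. A linear model with 1 mean per group was fitted to all 18 arrays, so that the groups shared 1 estimate of the spread per gene with 12 residual degrees of freedom and 3.89 prior degrees of freedom. PCB126 was compared with DMSO at each time, and DMSO at 72 h with DMSO at 6 h, by two-sided moderated tests without an intensity trend. A moderated F-test asked whether the effect of PCB126 differed between the times. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison and a gene was called at an adjusted p under 0.05.

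Gene lists were tested with limma's camera (two-sided, preset correlation 0.01) and adjusted over the 23 lists of a comparison. Camera with a correlation estimated from the residuals, camera on ranks and fry were also computed. The lists held targets of the aryl hydrocarbon receptor (AhR battery), NRF2 antioxidant genes, other xenobiotic metabolism and transport, cell cycle, p53 targets, Wnt targets, YAP/TEAD targets, TGF-β/SMAD targets, BMP/ID targets, cell junctions, extracellular matrix, inflammation (NF-κB), and interferon response. Further lists held sterol synthesis, fatty acid synthesis, fatty acid oxidation (PPAR), ER stress and integrated stress response, hypoxia and glycolysis, and circadian clock genes, and markers of hepatocytes, cholangiocytes, mesenchymal cells and myofibroblasts, and blood and endothelial cells. Of 458 members, 421 were measured (394 matched by symbol, 11 by an older symbol and 16 by a RefSeq synonym).

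The comparisons, tests, lists, most other settings and the rule for named genes were chosen before the data were examined. The rule named, per time, the 7 largest rises and 7 largest falls among called genes whose 3 treated values all lay on 1 side of the 3 control values, every measured member of the AhR battery, and up to 3 called members of each other list with the largest changes. For the comparison of times and for the control cultures it named the 5 largest differences per direction. A few further genes are named in the closing section and are said there to have been chosen after their values were seen.

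The results were also computed with the replicate number as a block, the mean over probe sets, bright probe sets or bright genes alone (above the median probe set level of 4.03) and genes with at least 4 probe sets. Further settings were 2 other scalings between arrays, an intensity trend, a fit with the compared groups alone, other settings of camera, and leaving out each array in turn. After the data had been seen, centring on the median of the genes, leaving out replicate 1 of PCB126 at 24 h and at 72 h together, and array quality weights were added. The tests were also run on simulated data with 16988 genes and known changes. At 6 h the simulated test recovered 13.4% of genes changed by 0.5 on the log2 scale, 62.7% of those changed by 1 and 98.5% of those changed by 2, and 5.69% of its calls were false. At 24 h these values were 17.9%, 68.7%, 97.0% and 8.27%, at 72 h 13.4%, 65.7%, 95.5% and 5.69%, and for the control cultures 13.4%, 70.1%, 97.0% and 7.69%. Each comparison was simulated 1 time with the same baseline and spread and with 67, 67 and 66 genes changed by 0.5, 1 and 2. These rates therefore differ by the random draw and do not describe single times. Noise was drawn separately for each gene, and fewer genes changed than were called in the data at 24 h and 72 h. The simulated F-test recovered 89.5% of differences of 2, with 4.28% false calls.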

Results

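The data are 18 exon arrays of confluent WB-F344 cells, with 3 arrays for each of 6 groups: DMSO and PCB126 at 6, 24 and 72 h. PCB126 is a coplanar, dioxin-like polychlorinated biphenyl and a ligand of the aryl hydrocarbon receptor (AhR), and the series compares it with its vehicle at each time. Over all probe sets the array medians lay between 4.06 and 4.15 on the log2 scale, and over the 16988 genes between 6.19 and 6.54. The first 4 principal components held 21.2%, 12.2%, 9.13% and 5.53% of the variance between arrays. Replicate pairs of 1 group differed by an SD of 0.352 to 0.518 over genes, with the largest value between replicates 1 and 2 of PCB126 at 72 h. These 2 arrays also had the widest spread of relative log expression (interquartile range 0.461 and 0.475). The median standard error of a fold change was 0.183.

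At 6 h, members of the AhR battery rose with PCB126. Aldh3a1, an aldehyde dehydrogenase of the AhR battery, went from 6.64 ± 0.26 to 11.26 ± 0.16 (log2, SD, n = 3 arrays each), a 24.7-fold rise. Cyp1a1, the classical AhR-induced cytochrome P450, rose 7.48-fold, from 4.07 ± 0.21 to 6.97 ± 0.45. Nqo1, a quinone reductase, rose by 2.09 (SE 0.146), Cyp1b1 by 1.89 (SE 0.217) and Adh7, a retinol-oxidising alcohol dehydrogenase, by 1.77 (SE 0.229). Foxq1, a forkhead transcription factor measured by 1 probe set, rose by 1.84, and Gfra1, a GDNF co-receptor, by 1.68. The largest falls were those of Igfbp5, which binds insulin-like growth factors (log2 change -1.52, SE 0.151, adjusted p = 6.51e-05), Adora2a, an adenosine receptor (-1.17), and Clic5, a chloride channel protein (-1.11). Also lower were Enpp2, which encodes the lysophospholipase autotaxin (-1.03), Garnl4 (current symbol Rap1gap2, -1.01), the duct keratin Krt19 (-1.01) and Podxl, a sialomucin (-0.96). In all, 84 of 16988 genes were called by limma, 43 higher and 41 lower, of which 24 and 6 changed at least 2-fold. The share of higher genes was 51.2%, and between 55.8% and 78.1% when 1 of the 6 arrays was left out.

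Of the 14 measured members of the AhR battery, 6 rose at 6 h (Aldh3a1, Cyp1a1, Nqo1, Cyp1b1, Tiparp and Ahrr), and 7 when adjusted over the list alone. Tiparp, a poly-ADP-ribose polymerase, rose by 1.27 and the AhR repressor Ahrr by 1.23. Camera called the list (adjusted p = 1.75e-19, and 1.23e-04 with an estimated correlation). Outside the battery, Ptgs2, the inducible cyclooxygenase, rose by 1.03, the immunoproteasome subunit Psmb9 by 1.04 and Cyr61 (current symbol Ccn1), a matricellular YAP target, by 0.80, while Cyp4b1 fell (-0.78). A further 5 lists moved with 0 members called by limma over all genes. Sterol synthesis was higher (16 measured, median 0.17, 0 members adjusted over the list alone, adjusted p = 9.49e-04). Cell cycle (40 measured, median -0.15, 1 lower adjusted over the list alone, adjusted p = 0.00244) and cell junctions (22 measured, median -0.14, 4 lower adjusted over the list alone, 0.0157) were lower. So were BMP/ID targets (13 measured, median -0.18, 3 lower adjusted over the list alone, 0.0298) and extracellular matrix (35 measured, median -0.13, 0 adjusted over the list alone, 0.0298). With an estimated correlation none of these 5 calls held (adjusted p = 0.323, 0.601, 0.215, 0.179 and 0.545 in that order). With fry, sterol synthesis, cell cycle and extracellular matrix did not pass either (adjusted p = 0.131, 0.327 and 0.198). Cell junctions and BMP/ID targets passed with fry (0.0112 each). At an unadjusted p under 0.05 limma gave 1412 genes at 6 h.

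Leaving out any 1 of the 6 arrays compared at 6 h lowered the count of 84 genes. Without DMSO 6 h replicates 1, 2 and 3 it was 32 (78.1% higher), 43 (67.4%) and 43 (58.1%). Without PCB126 6 h replicates 1, 2 and 3 it was 38 (68.4%), 43 (55.8%) and 44 (70.5%). A fit with the compared groups alone called 11, and 13 of 20 named calls were lost. Krt19 lost its call without any 1 of the 6 arrays (adjusted p 0.0591 to 0.159) and Cyp4b1 without 5 of them (up to 0.0945). Enpp2 and Psmb9 lost it without 4 (up to 0.0961 and 0.0713, both without PCB126 6 h replicate 1) and Garnl4 without 2 (up to 0.0601 without DMSO 6 h replicate 1). The cell cycle list lost its call without PCB126 6 h replicate 1 (adjusted p = 0.2895) or DMSO 6 h replicate 2 (0.112), and cell junctions without PCB126 6 h replicate 2 (0.0527). BMP/ID targets lost it without DMSO 6 h replicate 2 (0.112) or PCB126 6 h replicate 2 or 3 (0.0982 and 0.110). Extracellular matrix lost it without DMSO 6 h replicate 1 or 2 or PCB126 6 h replicate 2 or 3 (0.0535, 0.107, 0.0674 and 0.106).

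**Figure D1:**
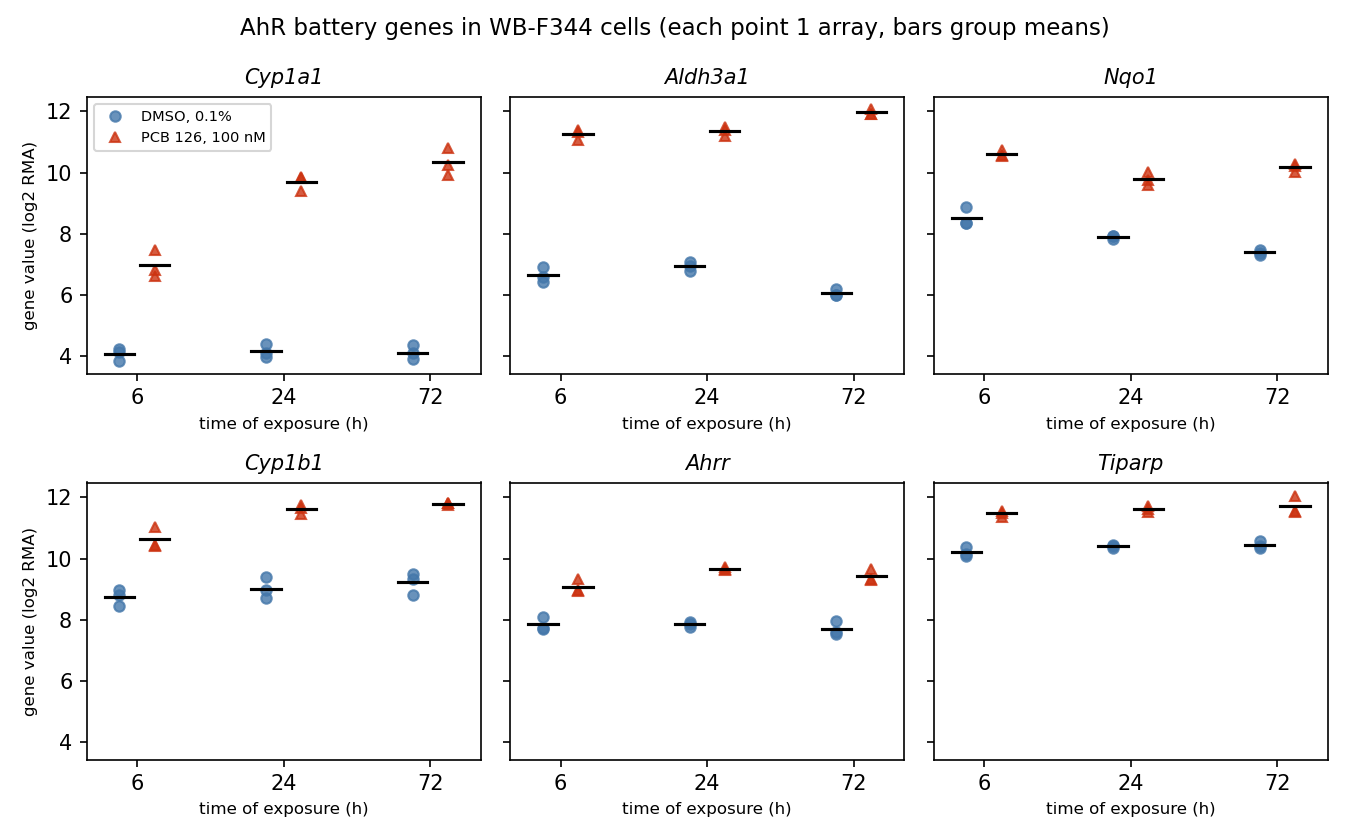
Gene values (log2 RMA) of 6 AhR battery genes against time of exposure in hours, with 1 point per array (circles DMSO, triangles PCB126, 3 each) and bars at the group means. For each gene and time all 3 PCB126 arrays lie above all 3 DMSO arrays, and Cyp1a1 rises from 6.97 at 6 h to 10.33 at 72 h with PCB126 and stays between 4.07 and 4.15 with DMSO.

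At 24 h, Cyp1a1 stood 46.7-fold above DMSO (4.15 ± 0.23 against 9.69 ± 0.26, n = 3 arrays each) and Aldh3a1 21.5-fold. Akr1c14, a hydroxysteroid dehydrogenase with close paralogs, rose by 3.75 (SE 0.454) and Kcnj2, a potassium channel measured by 1 probe set, by 2.88 (SE 0.606). Cyp1b1 rose by 2.61, Foxq1 by 2.36 and Adh7 by 2.23. Among the largest falls the growth factor gene Igf1 changed by -2.74 (7.55 ± 0.09 to 4.80 ± 0.37), Igfbp5 by -2.74 (SE 0.151) and the small proteoglycan Ogn by -2.33 (SE 0.240). Adora2a fell as well (-2.75, SE 0.143), as did Gpr160, an orphan receptor measured by 2 probe sets (-2.71), the lipopolysaccharide-binding protein gene Lbp (-2.43) and Gcnt1, a glycosyltransferase (-2.20). Limma called 823 genes, 289 higher and 534 lower, of which 66 and 129 changed at least 2-fold. The share of higher genes was 35.1%, between 29.4% and 40.8% when 1 of the 6 arrays was left out, and 44.6% (422 higher and 525 lower) with centring on the median of the genes.

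The AhR battery had 7 members higher at 24 h (9 adjusted over the list alone), with an adjusted p of 4.51e-16 (3.58e-04 with an estimated correlation). They were the same 6 as at 6 h and Nfe2l2, which encodes NRF2 and rose by 0.60 (adjusted p = 0.00246). Of 40 measured cell cycle genes 20 rose, 35 adjusted over the list alone, with a list median of 0.60 (adjusted p = 6.02e-27, and 0.0480 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, rose by 0.93, the mitotic cyclin Ccnb2 by 0.92 and the replication licensing factor Mcm5 by 0.91 (SE 0.122). Of 22 cell junction genes 5 fell (8 adjusted over the list alone), with an adjusted p of 9.20e-05 (0.0457 with an estimated correlation). Among them were the cadherins Cdh3 (-0.97), Cdh11 (-0.80) and Cdh13 (-0.63). Of 16 genes on the fatty acid oxidation (PPAR) list 6 fell (7 adjusted over the list alone). Among them were Angptl4 (-0.98), Pdk4 (-0.78) and Cpt1a, which carries fatty acids into mitochondria (-0.76). The list's adjusted p was 7.19e-05, and 0.0908 with an estimated correlation. Sterol synthesis was higher with 2 of 16 members called, Stard4 (0.73) and Sqle (0.48), and 6 adjusted over the list alone (adjusted p = 1.43e-05, and 0.109 with an estimated correlation). Centring on the median of the genes gave 6 called members.

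A further 5 lists were lower at 24 h with the preset correlation and were not called with an estimated correlation. With fry all 10 lists called at 24 h passed (highest adjusted p = 0.0165, for extracellular matrix and interferon response). Of the extracellular matrix genes Postn (-1.76) and Fbn1 (-0.78) fell and Fbln2 rose (0.89). The list had 1 higher and 4 lower of 35, 1 and 9 adjusted over the list alone, and an adjusted p of 0.0119 (0.306 with an estimated correlation). The inflammation list had 1 member higher and 4 lower of 22, the same adjusted over the list alone (adjusted p = 0.0293, and 0.0908 with an estimated correlation). Vcam1, a leukocyte adhesion molecule (-1.52), and the chemokine Ccl7 (5.33 to 4.33) fell while Ptgs2 rose by 1.35. Among 21 interferon response genes Mx2 (-1.61) and Mx1 (-1.05) fell and Psmb9 rose (1.24). Adjusted over the list alone 3 were higher and 5 lower (adjusted p = 0.0333, and 0.212 with an estimated correlation). BMP/ID targets had 2 of 13 members lower, Id4 (-1.12) and Smad6 (-0.64), and 2 adjusted over the list alone (adjusted p = 0.0293, and 0.0908 with an estimated correlation). TGF-β/SMAD targets had 1 of 13 lower, Tgfb3 (-1.05), and 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.0333, and 0.139 with an estimated correlation).

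The count at 24 h was 449 without DMSO replicate 1, 495 without PCB126 replicate 1, 536 without DMSO replicate 3 and 453 with the compared groups alone, where 16 of 65 named calls were lost. Without replicate 1 of PCB126 at both 24 h and 72 h it was 624. Arntl, Krt18 and Pgk1 lost their calls without any 1 of the 6 arrays (adjusted p up to 0.166, 0.0973 and 0.0984). Cdh13, Atf3, Cd14, Dbp, F3 and Gadd45a lost theirs without 5 (up to 0.161, 0.173, 0.162, 0.155, 0.179 and 0.168). Ccl7, Pdk4, Sesn1, Sqle and Sult1a1 lost theirs without 4 (up to 0.100, 0.111, 0.131, 0.121 and 0.0863) and Gclc without 3 (up to 0.0828). Angptl4 and Rrm2 were lost without 2 (up to 0.0672 and 0.0740, both without DMSO 24 h replicate 1). Kcnj2, Fbn1 and Krt19 were lost without 1 (0.0576 without DMSO replicate 3, 0.0517 without PCB126 replicate 1 and 0.0511 without DMSO replicate 1). Without DMSO 24 h replicate 1 the inflammation, interferon and TGF-β lists were not called (adjusted p = 0.1035, 0.1349 and 0.1336). Without PCB126 24 h replicate 2, which left 6 lists, these 3 and BMP/ID targets were not called (0.0542, 0.0758, 0.0542 and 0.0511). TGF-β targets also lost the call without PCB126 24 h replicate 3 (0.0842), and extracellular matrix without that array or DMSO 24 h replicate 2 (0.0506 and 0.1445).

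Smaller changes at 24 h concerned members of lists, most of which camera did not call as a whole. The clock genes Arntl (current symbol Bmal1, -0.78) and Dbp (-0.67) fell and Per3 rose (0.70). The water channel Aqp1 (11.51 to 10.51), Krt19 (-0.95) and Krt18 (-0.69) fell among cholangiocyte markers. Among blood and endothelial markers the endothelial receptor kinase Tek (-1.31) and the lipopolysaccharide co-receptor Cd14 (-0.63) fell. Cyp2e1, a cytochrome P450 of hepatocytes, changed by -1.23. The intermediate filament gene Vim rose by 0.67. Gsta4, a glutathione transferase on the NRF2 list, fell (-1.35) while Gclc, a subunit of the rate-limiting enzyme of glutathione synthesis, rose (0.56). Cyp4b1 (-0.93), Sult1a1 (-0.80) and Gstm1 (-0.67) fell among other xenobiotic genes. The cyclin-dependent kinase inhibitor Cdkn1a rose by 0.68 while Sesn1 (-0.64) and Gadd45a (-0.62) fell. Among YAP/TEAD targets Cyr61 rose by 0.75 while Nt5e (-0.88) and F3, tissue factor, (-0.66) fell. The stress transcription factor Atf3 rose by 0.94, the glycolytic enzyme Pgk1 by 0.47, and Gpam, which starts glycerolipid synthesis, fell (-0.53).

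At 72 h, Cyp1a1 reached 10.33 ± 0.46 against 4.11 ± 0.24 (74.4-fold, n = 3 arrays each) and Aldh3a1 11.97 ± 0.09 against 6.06 ± 0.10 (60.1-fold). Akr1c14 rose by 4.36 (SE 0.454), Foxq1 by 3.15, Kcnj2 by 2.92, Nqo1 by 2.78 (SE 0.146) and the mitochondrial creatine kinase Ckmt1 by 2.70 (SE 0.129). Igf1 showed the largest fall (-3.28, SE 0.244), from 7.57 ± 0.21 to 4.29 ± 0.39, followed by Adora2a (-3.25), Clic5 (-3.00), Ogn (-2.83), Cyp2e1 (-2.67), Gpr160 (-2.55) and the matrix protease Adamts9 (-2.39, SE 0.124). Limma called 1264 genes, 560 higher and 704 lower, of which 130 and 195 changed at least 2-fold. The share of higher genes among the calls was 44.3%. It was 33.3% of 1149 without PCB126 72 h replicate 1, 56.4% of 1152 without PCB126 72 h replicate 2, and 33.7% of 1202 without replicate 1 of PCB126 at 24 h and 72 h.

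**Figure D2:**
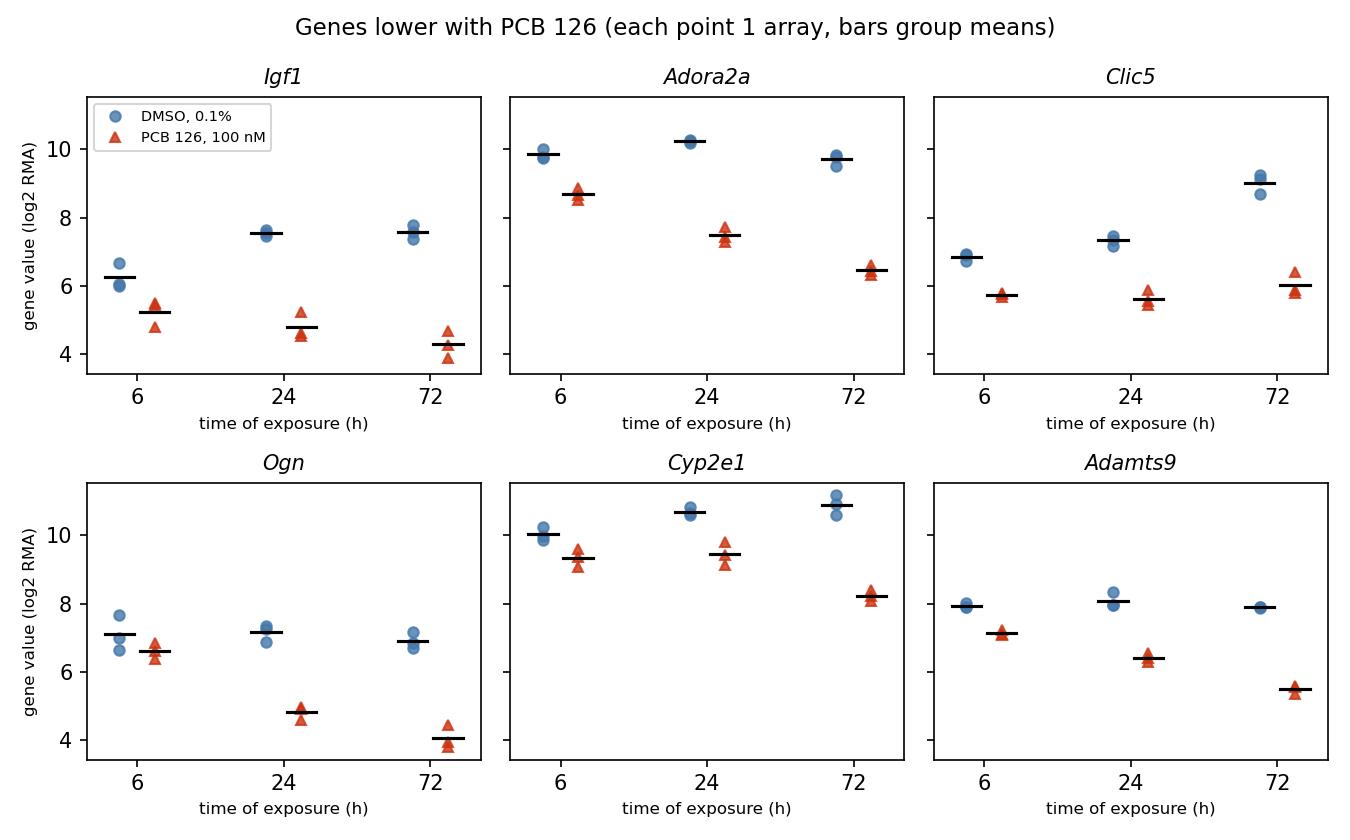
Gene values (log2 RMA) of 6 of the genes with the largest falls at 72 h against time of exposure in hours, with 1 point per array (circles DMSO, triangles PCB126, 3 each) and bars at the group means. With PCB126 Adora2a goes from 8.68 at 6 h to 6.45 at 72 h, while its DMSO means lie between 9.70 and 10.24, and Clic5 goes from 6.86 to 9.02 with DMSO and is at 6.02 with PCB126 at 72 h.

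Of the AhR battery 7 members rose at 72 h, 8 adjusted over the list alone (adjusted p = 3.66e-11, and 0.00228 with an estimated correlation). Cyp1b1 rose by 2.58, Ahrr by 1.73, Tiparp by 1.28 and Cyp2s1 by 0.80 (adjusted p = 0.0420, lost without 4 of the 6 arrays, up to 0.2002 without DMSO 72 h replicate 3). Nfe2l2 was at 0.31 (adjusted p = 0.103) and at 6 h at 0.38 (0.183). The battery members that passed at no time were Ahr itself (-0.20, 0.10 and -0.22 at 6, 24 and 72 h), Cyp1a2 (0.23, -0.26 and 0.11) and Gsta2 (-0.48, -0.07 and -0.07). The others were Xdh (0.24, -0.04 and -0.26), Ugt1a6 with 2 probe sets (0.07, 0.53 and 0.26) and Ugt1a7c with 1 (0.34, 0.03 and -0.12). Without DMSO 24 h replicate 3 Ugt1a6 gained a call at 24 h (adjusted p = 0.02945), and without DMSO 72 h replicate 3 Nfe2l2 gained one at 72 h (0.0261).

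Cell cycle and sterol synthesis genes were higher than in DMSO at 72 h. In the DMSO cultures both lists were lower at 72 h than at 6 h (medians -0.33 and -0.41, and -0.18 and -0.26 with centring on the median of the genes). The DMSO 72 h arrays enter both comparisons, so low values there would give both a fall in the controls and a rise with PCB126. Those control calls did not hold with an estimated correlation (adjusted p = 0.503 and 0.334) and passed with fry (0.039 and 0.001475). Of 40 cell cycle genes 27 rose, 33 adjusted over the list alone, with a median of 0.69 (adjusted p = 1.70e-23, and 0.0363 with an estimated correlation). Among them were Cdc6, which loads the replicative helicase (1.13), and the mitotic genes Kif23 (1.11) and Ttk (1.06). Of 16 sterol synthesis genes 12 rose, 14 adjusted over the list alone, with a median of 0.74 (adjusted p = 1.22e-14, and 0.0125 with an estimated correlation). Idi1 rose by 1.07, Sc4mol (current symbol Msmo1) by 0.89 and Lss, lanosterol synthase, by 0.89. Fatty acid synthesis had 6 of 11 members higher and 1 lower, 7 and 3 adjusted over the list alone (adjusted p = 0.00448, and 0.246 with an estimated correlation). Fads2 (0.95), Acsl3 (0.76) and Elovl6 (0.76) were higher. The fatty acid oxidation (PPAR) list was lower, with Cpt1a (-0.72) and Pdk4 (-0.64) called of 16 and 1 higher and 6 lower adjusted over the list alone (adjusted p = 0.00590, and 0.246 with an estimated correlation). Hypoxia and glycolysis was higher with 3 of 18 members called, and 3 adjusted over the list alone (adjusted p = 0.00448, and 0.0363 with an estimated correlation). They were Ldha (0.83), Pgk1 (0.60) and Eno1 (0.46), all enzymes of glycolysis or lactate formation.

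BMP/ID targets and cell junction genes fell at 72 h. Of 13 BMP/ID targets 4 fell, 5 adjusted over the list alone (adjusted p = 6.18e-04, and 0.0125 with an estimated correlation). Id4, an inhibitor of basic helix-loop-helix factors, was at -1.88 (SE 0.152), the inhibitory SMAD gene Smad6 at -1.18 and the ligand Bmp4 at -0.61. Cell junctions had 5 of 22 members lower, 6 adjusted over the list alone (adjusted p = 9.78e-05, and 0.0216 with an estimated correlation). Cdh3 (-1.28), Cdh11 (-1.09) and the tight junction scaffold Tjp1 (-0.78) were among them. In the extracellular matrix list 2 of 35 rose and 8 fell, 2 and 11 adjusted over the list alone (adjusted p = 6.53e-04, and 0.246 with an estimated correlation). Postn (-1.70) and the metalloproteinase inhibitor Timp3 (-1.39, with 4 of 6 probe sets lower) fell and Fbln2 rose (1.47). All 9 list calls at 72 h were kept without each single array. With fry all 9 passed (highest adjusted p = 0.0107, for fatty acid oxidation).

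Members of lists that camera did not call at 72 h also changed. Ptgs2 rose by 1.82 while Vcam1 (-1.67) and complement C3 (-1.60) fell. Psmb9 rose by 1.56 and Irf1 by 0.63 while Irf9 fell (-0.57). The actin-binding protein gene Tagln rose by 1.62 and Vim by 1.15, and among cholangiocyte markers Krt8 rose by 1.08 while Aqp1 (-1.44) and Krt19 (-1.37) fell. Tek (-1.53) and Cd14 (-0.76) fell, as did the clock output genes Hlf (-1.68, with 2 of 3 probe sets lower) and Tef (-0.69), while Bhlhb3 (current symbol Bhlhe41) rose by 0.90. Gsta4 fell (-1.78) while Gclc (0.47) and Tkt (0.45) rose, and Gstm2 (-0.77) and Cyp4b1 (-0.66) fell. Tgfb3 (-1.09), Fn1 (-0.71) and Smad7 (-0.67), and the Wnt targets Ccnd1 (-0.75), Axin2 (-0.67) and Apcdd1 with 1 probe set (-0.60) fell. Cdkn1a rose by 1.05 while Sesn1 (-0.67) and Gadd45a (-0.58) fell. Ctgf (current symbol Ccn2) rose by 0.76 and the receptor kinase Axl by 0.63 while F3 fell (-0.97). Atf3 rose by 1.53. Of these and the preceding genes, Pdk4 lost its call without any 1 of the 6 arrays (adjusted p 0.0718 to 0.188) and Irf1 without 5 (up to 0.117). Eno1, Gadd45a, Irf9 and Tkt lost theirs without 4 (up to 0.0696, 0.164, 0.104 and 0.0882) and Gclc, Bhlhb3 and Tef without 3 (up to 0.1202, 0.115 and 0.0766). Sesn1 and Bmp4 lost theirs without 2 (up to 0.0696 and 0.0588) and Apcdd1 without DMSO 72 h replicate 1 (0.0685). With the compared groups alone 416 genes were called at 72 h, and 29 of 75 named calls were lost.

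**Figure D3:**
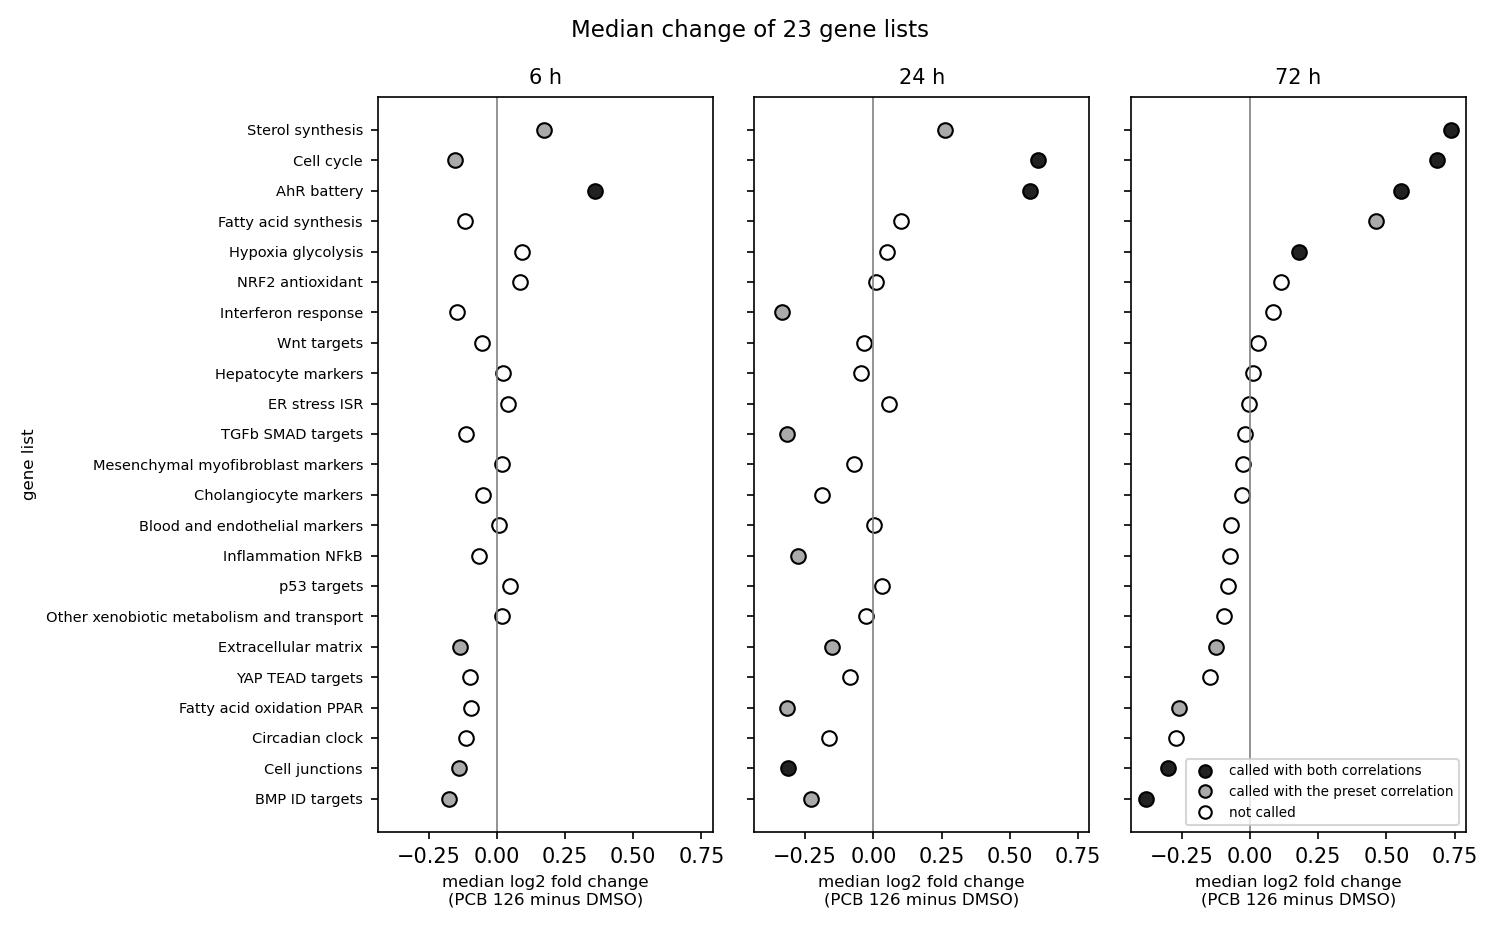
Median log2 fold change (PCB126 minus DMSO) of the members of 23 gene lists at 6, 24 and 72 h, ordered by the value at 72 h (black, called with the preset and with the estimated correlation; grey, with the preset correlation alone; open, not called). At 72 h the medians run from -0.38 (BMP/ID targets) to 0.74 (sterol synthesis), and the cell cycle list goes from -0.15 at 6 h to 0.69.

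The lists that camera called at none of the 3 times had the following medians and counts at 72 h, with the counts adjusted over the list alone in brackets. NRF2 antioxidant genes had a median of 0.11 with 2 higher and 1 lower of 18 (3 and 2) and other xenobiotic genes -0.10 with 0 and 2 of 20 (0 and 2). P53 targets had a median of -0.08 with 1 and 2 of 18 (2 and 3), Wnt targets of 0.03 with 0 and 4 of 17 (2 and 5) and YAP/TEAD targets -0.15 with 4 and 1 of 20 (4 and 4). ER stress genes had a median of -0.003 with 1 and 0 of 18 (3 and 0). Clock genes had one of -0.27 with 2 and 3 of 13 (2 and 6), at an adjusted p of 0.0615 (0.0382 without PCB126 replicate 1 or 0.0492 without DMSO replicate 2). Markers of liver and other cell types gave no list called by camera at any time. Hepatocyte markers had 0 higher and 1 lower of 17 (0 and 1, adjusted p = 0.719) and cholangiocyte markers 1 and 3 of 12 (1 and 3, 0.303). Mesenchymal and myofibroblast markers had 2 and 0 of 12 (2 and 0, adjusted p = 0.214) and blood and endothelial markers 0 and 2 of 15 (0 and 2, 0.339). At 72 h the median, the mean and the test differed in sign for the p53, Wnt, ER stress, hepatocyte and mesenchymal lists. With fry, the mesenchymal, blood and cholangiocyte lists passed at 72 h (adjusted p = 5e-04, 0.00781 and 0.0107), and hepatocyte markers did not (0.0925). Fry also passed the clock and TGF-β/SMAD lists at 72 h (0.0236 and 0.00663). At 24 h it passed cholangiocyte markers (0.0165) and other xenobiotic genes (0.0304).

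Most genes called early were called again in the same direction later. The group means compared share no arrays, but the tests share 1 estimate of the spread per gene. The counts expected for independent lists below do not allow for that shared estimate. Of the 43 genes higher at 6 h, 37 were also higher at 24 h (0.732 expected for independent lists) and 38 at 72 h (1.42 expected). Of the 41 lower genes, 39 were lower at 24 h (1.29 expected) and 37 at 72 h (1.70 expected). From 24 h to 72 h, 221 of 289 higher genes (9.53 expected) and 379 of 534 lower genes (22.1 expected) were shared, and 1 gene was called in opposite directions. At all 3 times 73 genes were called, 37 higher and 36 lower, and 1492 at 1 time or more. All 3 treated arrays lay on 1 side of all 3 DMSO arrays for 16.9%, 21.8% and 20.2% of genes at 6, 24 and 72 h, where chance gives 10%.

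The effect of PCB126 differed between the times for 96 genes by the moderated F-test, 41 with a higher and 55 with a lower signed effect at 72 h than at 6 h. The effect at 72 h exceeded that at 6 h by 3.32 for Cyp1a1 (SE 0.346, adjusted p = 4.98e-04) and by 3.23 for Akr1c14 (SE 0.642, adjusted p = 0.04995). It exceeded it by 1.93 for Cacnb2, a calcium channel subunit (SE 0.307, adjusted p = 0.0194), by 1.87 for the ubiquitin ligase Nedd4l (SE 0.284, 0.0130) and by 1.79 for Gdf2, which encodes BMP9 (SE 0.327, 0.0415). It was lower at 72 h by a difference of -2.35 for Ogn (adjusted p = 0.00687), -2.28 for Igf1 (0.00945), -2.08 for Adora2a (4.23e-04), -1.99 for Cyp2e1 (0.00487) and -1.89 for Clic5 (0.00462). The count fell by over 1.5 times without any 1 of 11 of the 18 arrays. It was 37 without DMSO 6 h replicate 2 or 3, 40 and 53 without PCB126 6 h replicates 1 and 3, and 44, 55 and 47 without DMSO 72 h replicates 1, 2 and 3. It was 48 and 60 without DMSO 24 h replicates 1 and 3, 57 without PCB126 24 h replicate 3 and 54 without PCB126 72 h replicate 3. Leaving out 1 array ended the call of Akr1c14 in 16 of 18 cases (adjusted p up to 0.139 without PCB126 6 h replicate 3), that of Gdf2 in 15 (up to 0.153 without DMSO 6 h replicate 2) and that of Cacnb2 in 3 (up to 0.0625 without DMSO 72 h replicate 3).

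The control cultures changed between 6 h and 72 h. Lcp1, an actin-bundling protein gene, rose by 2.55 (5.18 ± 0.28 to 7.74 ± 0.01, n = 3 arrays each), the myosin-binding protein gene Mybpc1 by 2.32, the matrix glycoprotein gene Thbs2 by 2.26, Clic5 by 2.17 and Enpp2 by 2.02. The chemokine gene Cxcl13 fell (-2.12, SE 0.156), as did the basement membrane gene Nid1 (-1.79), the glycolytic enzyme Aldoc (-1.75), the integrin Itgb5 (-1.75) and Enc1 (-1.62). Limma called 703 genes, 147 higher and 556 lower, with groups apart for 26.0% of genes where chance gives 10%. Centring the arrays on the median of the genes, which moved the median difference of all genes from -0.05 to 0.10, gave 312 higher and 219 lower of 531, of which 366 were shared with the 703. The share of higher genes was 20.9%, and 31.7% of 161 without DMSO 6 h replicate 2. The count was 293 and 373 without DMSO 6 h replicates 1 and 3, 245 and 205 without DMSO 72 h replicates 1 and 3, and 73 with the compared groups alone.

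Among the lists in the control cultures, ER stress was higher with 1 of 18 called (5 adjusted over the list alone), at an adjusted p of 0.00115 (0.205 with an estimated correlation). Cell cycle was lower with 8 of 40 called (16 adjusted over the list alone), at an adjusted p of 2.67e-05 (0.503 with an estimated correlation). Sterol synthesis had 4 of 16 lower (9 adjusted over the list alone) at 2.07e-05, and fatty acid synthesis 6 of 11 (8 lower and 1 higher adjusted over the list alone) at 0.00116. Extracellular matrix had 6 of 35 lower (8 adjusted over the list alone) at 0.0190, and interferon response 4 of 21 (6 adjusted over the list alone) at 0.0364. With an estimated correlation none of the 6 calls held (adjusted p = 0.334, 0.349, 0.503 and 0.349 for these last 4 lists). With fry all 6 passed (adjusted p = 0.00863, 0.039, 0.001475, 0.001475, 0.00549 and 0.00386 in the order given). Camera on ranks kept ER stress (adjusted p = 0.0122), cell cycle and sterol synthesis (1.88e-04 each) and did not keep the others. Centring on the median of the genes kept all 6 calls with other member counts: 4 higher for ER stress, and 3, 3, 2, 4 and 2 lower for cell cycle, sterol synthesis, fatty acid synthesis, extracellular matrix and interferon response, with 1 higher for fatty acid synthesis and for extracellular matrix. Quantile normalisation gave 4 higher for ER stress and 5 lower for cell cycle. At 72 h PCB126 lowered Clic5 (-3.00), Enpp2 (-2.01), Mybpc1 (-1.90) and Thbs2 (-0.86) and raised Nid1 (1.03) and Itgb5 (0.89), while Lcp1 (-0.04), Cxcl13 (-0.26), Aldoc (0.34) and Enc1 (0.84) did not pass. These genes were named by the control comparison, which shares the DMSO 72 h arrays with these values.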

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

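The tests of the opposite deviation by olfactory receptor genes and by a trend on brightness, those of the control cultures' genes at 24 h and of lists at an unadjusted p, the splits for the difference between times and the share of genes with probe sets in both directions were chosen only after the results had been seen, and the other tests were written down before their values were computed.

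The F-test found 96 genes whose effect differed between the times. Beyond the genes given with the comparison of times (Cyp1a1 3.32, Akr1c14 3.23, Cacnb2 1.93, Nedd4l 1.87, Gdf2 1.79, Ogn -2.35, Igf1 -2.28, Adora2a -2.08, Cyp2e1 -1.99 and Clic5 -1.89, each 72 h minus 6 h on the log2 scale), the effect was higher at 72 h for Ckmt1 (1.51), Aldh3a1 (1.28), Fbln2 (1.19) and Mcm5 (0.89). It was lower for Adamts9 (-1.60), Mybpc1 (-1.32), Id4 (-1.22), Lbp (-1.15), Podxl (-0.70) and Igfbp5 (-0.48). Igfbp5 and Lbp had their largest fall at 24 h and Mcm5 its largest rise (-1.22, -1.92 and 1.08, each 24 h minus 6 h). Leaving out 1 of the 18 arrays ended the call for Igfbp5 and Mybpc1 in 14 cases, Id4 in 12 and Fbln2 in 10, each with adjusted p up to 0.102. It ended it for Podxl in 10 and Mcm5 in 3 (up to 0.0790 and 0.0645), and for Akr1c14, Gdf2 and Cacnb2 in 16, 15 and 3 (up to 0.139, 0.153 and 0.0625). The arrays were also split within each time after each gene's mean effect over the times was taken off the PCB126 arrays, which leaves the F-test as it is. Of 100 such splits only the real one gave as many genes (1 of 100, where the highest other gave 58), and 91 of the 99 others gave 0. Effects particular to 1 time stayed in the arrays, and in mixed splits they widen the spread and lower the count. The splits therefore cannot exclude chance for this count.

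The effect on the cell cycle list was higher at 24 h than at 6 h, with a median difference of 0.76 (adjusted p = 8.00e-41, and 0.03495 with an estimated correlation). The difference between 72 h and 6 h was 0.84, with an adjusted p of 0.0646 with an estimated correlation. At 6 h alone, limma called 0 of the 40 members and the list's fall did not hold (adjusted p = 0.601 with an estimated correlation).

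Probe sets outside the gene values also differed from DMSO. Of 817479 probe sets without a gene symbol, 30 were called at 24 h (19 higher and 11 lower) and 165 at 72 h (83 higher and 82 lower), and of 3523 with several symbols 1, 15 and 42 were called at 6, 24 and 72 h.

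With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each case 1 of the 10, the real one, gave the highest count. The real splits called 84, 823 and 1264 genes at 6, 24 and 72 h and 703 in the control cultures, and the highest other splits 0, 1, 0 and 0. Every other split mixes arrays of both groups compared, so a real difference widens its spread and lowers its count. The low counts of the other splits are thus partly built in. The real splits called 6, 10 and 9 lists, and the highest others 3, 5 and 6.

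Replicates 1 and 2 of PCB126 at 72 h deviated from their group mean in opposite directions (r = -0.68 across genes, where 3 replicates give -0.50 by construction). The median over all genes also differed most between these arrays, by 0.150. A difference in signal range as the whole cause is argued against by the SD of their difference, which was 0.518 and stayed at 0.486 (95% interval 0.478 to 0.492) after a trend on brightness was removed, against up to 0.438 in other replicate pairs. An altered background stays open: the median of 1124 olfactory receptor genes differed by 0.014, but these lie near the floor (median level 2.66) and exclude nothing. A stronger response in 1 array as the whole cause is argued against by the slopes of the 72 h changes on the 24 h changes over 823 genes. They differed by 0.0345 between replicates 1 and 2 (1.07 and 1.03, with 0.988 in replicate 3). The SE of that difference (0.0136) takes the genes as independent, which they are not. Cyp1a1 alone stood 6.71, 6.14 and 5.80 above the DMSO mean in replicates 1, 2 and 3. A stronger response of single genes therefore stays open. No other biological explanation was tested, because the labels give no difference between the replicates, and another difference between the cultures stays open.

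Genes that rose from 6 h to 72 h in the control cultures were lower with PCB126: the 147 genes had a median change of -0.62 at 72 h, with 75 lower and 9 higher. The DMSO 72 h arrays enter both comparisons, and a simulation of unchanged groups gave -0.11 (-0.12 to -0.09). At 6 h they were at -0.01, where the simulation gave 0.11 (0.09 to 0.12), and at 24 h, where no array is shared, they were lower (median -0.19, p = 0.0357 with an estimated correlation), which argues against shared arrays as the whole cause. Centring on genes, which shifts all genes of an array alike, left a median of -0.15 at 24 h. It thus argues only against a uniform shift between arrays as the whole cause. Centring does not address scaling that depends on brightness, and the 147 genes were not chosen again after it. A candidate explanation is that PCB126 holds back part of the change of confluent cultures with time. Limma called 0 genes between DMSO at 24 h and at 6 h (987 at an unadjusted p under 0.05), so no list at the adjusted threshold shared no array. The 441 genes higher at an unadjusted p were lower with PCB126 at 72 h, with 99 called lower and 14 higher (median -0.10, camera p = 0.00818 with an estimated correlation). With 0 genes called after adjustment, chance alone could give most of the 987 genes at that threshold. Most of the 441 may therefore not have changed in the controls, which by itself would weaken a shift. The list went the way that holding back predicts. It was tested after the results had been seen, and the list of genes lower in DMSO at 24 h did not pass. The 441 genes therefore do not settle the question. Holding back remains a hypothesis.

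The 556 genes that fell in the controls had a median of 0.08 at 72 h. The simulation of shared arrays gave 0.07 (0.06 to 0.08), so shared arrays could give this rise of the median. Of the 556 genes 112 were called higher and 57 lower, against 560 and 704 of all 16988 genes. Called genes were not counted in the simulation, so these counts were not set against shared arrays. At 24 h the 556 genes were at -0.10 (camera p = 0.583 with an estimated correlation), where the simulation gave -0.0017 (-0.016 to 0.011). At 6 h they were at -0.18 (camera p = 0.131 with an estimated correlation), where it gave -0.07 (-0.08 to -0.06). Neither of these 2 values passed with an estimated correlation. The simulation drew the noise of each gene separately, so its ranges leave out deviations that genes share. With 0 genes called between DMSO at 24 h and at 6 h, holding back need not show at these times. The 2 values therefore decide nothing about shared arrays or holding back, which stays open for 72 h. Limma called 0 lower genes at 24 h. The 546 lower at an unadjusted p were at 0.11 at 72 h, with 104 called higher and 29 lower (camera p = 0.158 with an estimated correlation).

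Some genes had probe sets called in opposite directions at 72 h, and Pde11a, a phosphodiesterase chosen after its values were seen, had 16 higher (up to 1.08) and 5 lower (down to -1.38) of 32, with a gene value of -0.03 (adjusted p = 0.943). Such genes were 15 of 1181 with 2 or more called probe sets, or 1.27%, a share that false calls at the threshold could give for these genes as a set. Noise in dim probe sets stays open. Of the minority probe sets 22.2% (2 of 9) lay below the dim limit, but they come from 5 of the 15 genes, with 5 of the 9 from Pde11a, and the other genes had 1 probe set each way. Pde11a was the 1 gene with at least 2 called probe sets each way, and a change in the transcripts made from it was not tested.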

How the results depend on the processing

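Centring on gene medians, array quality weights and leaving out replicate 1 of PCB126 at 24 h and 72 h together were chosen after the data had been seen. For single genes, 3126 of 3399 alternative values kept their direction and side of the threshold, 240 lost the call, 7 gained one and 26 turned sign. For single lists 1241 of 1357 kept both, 45 lost it, 23 gained one and 48 turned sign. The values that turned were called in neither setting (lowest adjusted p under the alternative 0.762 for genes and 0.640 for lists). Means over probe sets gave 178, 1256 and 1346 genes at 6 h, at 24 h and in the control cultures, and 210 for the difference between times; the cause was not tested. The latter was 148 with bright genes alone, 170 with an intensity trend, 152 with gene-median centring and 306 with array quality weights, which also gave 169 at 6 h and 1304 in the controls; the cause was not tested. A fit with the compared groups alone, which leaves fewer samples to estimate the spread, gave 11, 453 and 416 genes at 6, 24 and 72 h and 73 in the controls. An estimated correlation left 1 list at 6 h and 3 at 24 h. Leaving out 1 array gave 32 to 44, 449 to 623 and 885 to 1152 genes at 6, 24 and 72 h, 161 to 543 in the controls, 37 to 104 for the difference between times, and 3 to 6, 6 to 11 and 9 to 10 lists. Lists at 6 h came to 3 without DMSO or PCB126 replicate 2. The replicate number as a block gave 77, 878 and 1316 genes, 790 in the controls, 119 for the difference between times and 7, 10 and 10 lists. It did not call Atf3 at 24 h, Arntl at 24 h, Cd14 at 24 h or Pdk4 at 72 h (adjusted p = 0.0602, 0.0502, 0.0530 and 0.0649) and called Hypoxia and glycolysis at 6 h (0.0492) and the clock list at 72 h (0.0498). The labels do not say what the numbers mark, so the samples are taken to share only a number. Deviations of same-numbered samples correlated at 0.09, 0.05 and 0.16 at 6 h, 0.08, 0.17 and 0.09 at 24 h, and 0.04, 0.07 and 0.004 at 72 h. Over genes above the dim limit these were 0.15, 0.08 and 0.22, 0.11, 0.27 and 0.16, and 0.07, 0.12 and -0.01, and 8 of 9 samples correlated best with their own number, a hint from the data alone. Hypoxia and glycolysis gained a call at 6 h with gene-median centring (adjusted p = 0.0402) and, with quantile normalisation, at 6 h and 24 h (0.0382 and 0.0460). These calls and those gained with the block used the preset correlation. In the main fit with an estimated correlation Hypoxia and glycolysis was at 0.231 at 6 h and 0.160 at 24 h. The clock list was at 0.378 at 72 h in that setting. Signal over background limits what can be said of dim genes.

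The genes that turned sign are AhR battery members without a call. With bright probe sets alone Cyp1a2 came to 0.10 at 24 h and -0.17 at 72 h, and Gsta2 to 0.13 and 0.027. Gene-median centring gave Xdh 0.00059 at 24 h. Array quality weights gave Xdh 0.0091 at 24 h, and Cyp1a2 -0.0025 and Ugt1a7c 0.098 at 72 h. Without replicate 1 of PCB126 at 24 h and 72 h Gsta2 came to 0.26 and 0.19, Xdh to 0.040 at 24 h and Cyp1a2 to -0.0083 at 72 h. Leaving out 1 array gave Ugt1a6 -0.089 to 0.23 at 6 h, and at 24 h Gsta2 -0.34 to 0.26, Ugt1a7c -0.19 to 0.19 and Xdh -0.11 to 0.04. At 72 h it gave Cyp1a2 -0.0083 to 0.19, Gsta2 -0.49 to 0.19 and Ugt1a7c -0.31 to 0.075. The cause was not tested.

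The lists that turned sign follow with adjusted p. Hepatocyte markers at 6 h turned with the block (0.999), quantile normalisation (0.881) and array weights (0.966), and at 72 h with ranks (0.951) and without both replicates 1 (0.651). P53 targets at 24 h turned with bright genes (0.928), 4 or more probe sets (0.729), centring on all probe sets (0.977), the compared groups (0.935), ranks (0.893), array weights (0.972) and without both replicates 1 (0.713). At 72 h they turned with means (0.892), bright probe sets (0.989) and array weights (0.978), the last also for YAP/TEAD targets. At 24 h, bright probe sets turned the YAP/TEAD, mesenchymal and blood lists (0.955, 0.954 and 0.711), ranks these and the Wnt list (0.893 each), and means the NRF2 list (0.905). At 6 h, ranks turned other xenobiotic genes (0.800) and bright genes the inflammation list (0.894). Leaving out 1 array turned 4 lists at 6 h: other xenobiotic genes (range 0.498 to 0.992), YAP/TEAD (0.623 to 0.977), inflammation (0.683 to 0.977) and hepatocyte (0.650 to 0.977). At 24 h it turned the NRF2 (0.705 to 0.982), p53 (0.705 to 0.966), Wnt (0.583 to 0.966), YAP/TEAD (0.264 to 0.983), hepatocyte (0.405 to 0.983) and blood lists (0.651 to 0.960). At 72 h it turned the YAP/TEAD (0.369 to 0.936) and hepatocyte lists (0.2445 to 0.961). The cause was not tested.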

Other observations

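All genes in this part were chosen after their values were seen, and no test here was planned for them alone.

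Sox17, an endodermal transcription factor, rose at each time, by 0.99, 1.44 and 2.49 on the log2 scale at 6, 24 and 72 h (SE 0.161), from 6.33 ± 0.26 to 8.83 ± 0.16 at 72 h (SD, n = 3 arrays each), and its effect differed between times (adjusted p = 0.0115). At 6 h the call of Sox17 (adjusted p = 0.00768) was lost without 2 of the 6 arrays, with 0.0595 without DMSO replicate 1. Fst, which encodes the activin and BMP antagonist follistatin, rose by 1.23, 1.52 and 1.69 (SE 0.126), and the Notch target Hes1 rose by 1.22 at 24 h and 1.52 at 72 h, with 0.58 at 6 h not passing (adjusted p = 0.267). Hbegf, an EGF receptor ligand, rose by 0.92 and 1.35 at 24 and 72 h. Cpox, a haem synthesis enzyme, rose by 1.08, 1.80 and 1.94 (SE 0.117), and its effect differed between times by the F-test (adjusted p = 0.0376). The cyclin gene Ccnd2 rose by 0.81, 0.89 and 0.74, the first lost without PCB126 6 h replicate 1 or DMSO 6 h replicate 3 (adjusted p = 0.0577 and 0.0508).

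Kitlg, the ligand of the receptor Kit, was at -0.90 at 24 h and -2.04 at 72 h (SE 0.113; 11.17 ± 0.11 with DMSO and 9.13 ± 0.06 with PCB126 at 72 h, n = 3 arrays each), with -0.21 at 6 h not passing. Bmp6 changed by -1.01 and -1.83 (SE 0.123), the vasoconstrictor gene Edn1 by -0.97 and -1.83 (SE 0.182), the caveolar coat gene Cav1 by -0.87 and -1.72 (SE 0.130), and Arg1, the urea cycle arginase, by -1.27 and -1.99 (SE 0.132) at 24 and 72 h. Met, the hepatocyte growth factor receptor gene, was lower at 24 h (-1.08) and 72 h (-1.21), and at 6 h its value of -0.76 passed (adjusted p = 0.0406) but lost the call without any 1 of the 6 arrays (up to 0.187). By the F-test the effect on Kitlg, Cav1, Arg1, Bmp6 and Edn1 differed between times (adjusted p = 3.18e-04, 0.00310, 0.00487, 0.00662 and 0.0174).

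Of the gap and adherens junction genes, Gja1, which encodes connexin 43, had changes of -0.14, -0.48 and -0.30 (SE 0.230, 4 probe sets) at 6, 24 and 72 h and passed at none (adjusted p = 0.935, 0.340 and 0.559). Jup, plakoglobin, changed by -0.58 at 24 h and -0.53 at 72 h (SE 0.133; adjusted p = 0.0165 and 0.0213), and these calls were lost without 3 and 4 of the 6 arrays, with adjusted p up to 0.0835 without PCB126 24 h replicate 1 and 0.0901 without DMSO 72 h replicate 1.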
